A study of Mus musculus with 216 samples.

How the data were processed

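The series followed H3K9me3 and HP1β, the mark and one of the proteins of constitutive heterochromatin, by ChIP-seq in mouse embryonic stem cells. The cell line was named dTKO, with the genotype Suv39h1fl/fl; Suv39h2-/-; Setdb1fl/fl. Auxin at 100 µg/ml and dTAG13 at 0.5 µM, small molecules that send tagged proteins to degradation, were added at the start of the time course. Per the labels' protocols, each immunoprecipitation combined 20 µg of chromatin with 1.5 µg of Drosophila chromatin as a spike-in, and matched inputs were sequenced. The 216 samples are sequencing runs, not separate libraries. They fall into 4 kinds, namely H3K9me3, HP1β and an input for each, with 54 runs per kind and 9 at each of 6 times. Those 9 runs come from 3 biological repeats, with 1 library per repeat sequenced in 3 runs. The samples were grouped by the antibody or input named in their titles and by the time after treatment.

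The file used was the authors' deposited table of H3K9me3 domains, which gives a chromosome, a start, an end and a decay class in words (fast, intermediate, slow or residual) per domain. Per the submitters' processing notes, the tools were Bowtie2 2.3.4.1, SAMtools 1.1, deepTools and bedtools, and the genome builds named were mm10, dm6, mm9 and GRCm38. How reads in repeats were assigned, how domains were called, how signal was scaled by the spike-in, and where the limits between decay classes lay are not given in the sources used here. The labels name signal tracks that merge libraries and include reads with several matches; these tracks, the reads and the HP1β measurements were not analysed here. The table has 1 class per domain and 0 columns of sample values. The depth behind a class is therefore unknown, and no value has an error between cultures. Reads in repeated sequence can be placed on several copies, so the class of such a domain can reflect other copies too.

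All 43039 domains lay on a grid of 300 bp, with a shortest domain of 300 bp. Coordinates are on mm10 (GRCm38) and printed 1-based. They were compared with the GRCm38.p6 sequence and GENCODE vM21 genes: 0 domains ran past a chromosome end, and 0.00369% of bases in domains were N. The main set was the 42890 domains on chromosomes 1 to 19, X and Y. The 149 domains on 35 unplaced or unlocalized sequences were described separately.

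The tests, gene lists and rule for named genes were set before the data were examined. Widths and base composition were compared as differences of per-chromosome medians, for chromosomes with at least 5 domains in both classes. Their test was a two-sided sign-flip permutation test over chromosomes with 100000 resamples, whose smallest p is 1e-05. Overlaps of classes with chromosomes, annotation and gene lists used a two-sided circular shift test, a permutation test restricted to shifts. It moves the class labels along the ordered domains 10000 times, which keeps the clustering of classes, and its smallest p is 0.0001. Shares of neighbouring domains with the same class were compared with 10000 permutations of the labels within each chromosome. Adjusted p-values are Benjamini-Hochberg values within each family of tests, with a threshold of 0.05. Intervals of class shares are 95% intervals from 2000 resamples of whole chromosomes. An overlap needed 1 bp, a promoter reached 1 kb to either side of a protein-coding transcript start, and the proximal end was the first 10 Mb from the first domain of a chromosome. Coding-gene exons are exons of protein-coding transcripts and include their untranslated parts. The p-values measure spread between chromosomes or along the genome, not between cultures.

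For each domain, GC content, the observed over expected CpG ratio and the soft-masked (repeat) share were computed from the sequence. Copies of 31-mers in the genome, read every 100 bp of each domain, gave the share of unique 31-mers and the share found at least 100 times. Retroviral primer binding sites were 18-nt sequences complementary to the 3' ends of 403 annotated tRNA genes. Of 127 distinct sites, 2 that were shared by tRNAs of different amino acids were left out. The 19 gene lists were matched by symbol. The list of defensins takes every symbol that starts with Def and so holds Def8, which is not a defensin, and the ribosomal protein list holds the kinase gene Rps6kc1.

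Named genes are up to 3 members of each list per class with the most bases inside domains of that class. They also include the 10 protein-coding genes of at least 5 kb with the largest share inside fast domains, and likewise for slow domains, the genes of the H3K9 methylation machinery with a domain, and the 5 longest domains of each class. The comparison of levels over time that had been planned was not run, because the table has no value per time. The residual class was left out of the order of classes, since its rank is not given in the sources used here.

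The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The tests were tested on simulated data. With labels shifted at random, 3.88% of 2400 circular shift tests fell below the threshold. These labels came from the same kind of shift as the test, so a rate near the threshold was fixed in advance. Lists with fewer than 20 domains, such as the lineage regulators, and the chromosome tests were not among them. A slow share of 30% planted in 200 domains was recovered in 87 of 100 simulations, and a share of 40% in 100 of 100. All lists but the zinc finger genes met fewer than 200 domains, and no rarer class was planted. The rates therefore do not carry over to short lists or to the fast and residual classes. The sign-flip test over 20 chromosomes with an SD of 0.3 passed the threshold in 2 of 100 simulations without a difference and in 97 of 100 with a difference of 0.3. Alternatives left out the shortest domains (under 1500 bp, 8.50% of the main set), the sex chromosomes or each chromosome in turn, joined same-class neighbours less than 5 kb apart, or used covered length, means, midpoints, overlap of at least 50% of the domain, a 5 kb promoter, other proximal distances of 5 and 20 Mb, neighbours less than 50 kb apart, Fisher's exact test or labels permuted over all domains. Leaving out chromosomes 8 and 11, shifting labels within each chromosome, testing the lists among domains on a gene body or on a coding-gene exon only, and comparing the other pairs of classes in composition were added after the data were seen.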

Results

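Mouse embryonic stem cells of the dTKO line, in which H3K9 methyltransferases can be removed by auxin and dTAG13, were sampled by ChIP-seq at 0, 1, 3, 12, 24 and 48 h after the drugs were added. H3K9me3, HP1β and an input for each were sequenced in 54 runs per kind, 9 per time. The 9 runs are 3 biological repeats, with the library of each sequenced in 3 runs. The question was how fast H3K9me3 leaves different parts of the genome after the drugs are added. Loss of the methyltransferases was not measured here. The values used here are the authors' own division of H3K9me3 domains into 4 decay classes, made across the time course, with 1 class per domain and no value per library or time. Depth per domain is unknown, and no value below has a replicate error between cultures.

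Most H3K9me3 domains fell into the intermediate class. Of 42890 domains on chromosomes 1 to 19, X and Y, 30660 were intermediate (71.5%, 95% interval 65.2 to 76.6 over resampled chromosomes). Another 8772 were slow (20.5%, 16.8 to 24.7), 1960 residual (4.57%, 2.304 to 7.35) and 1498 fast (3.49%, 2.296 to 5.48). Domains covered 171.2 Mb, or 6.28% of the chromosomes, with a median gap of 29.7 kb between neighbours. Slow domains held 31.02% of the covered length, intermediate domains 61.4%, residual domains 4.86% and fast domains 2.72%. Of the residual domains, 1003 lay on chromosomes 8 and 11.

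Slow domains were longer than those of the other 3 classes. Their median width was 4.2 kb (quartiles 2.7 and 8.4 kb), against 2.7 kb for fast, intermediate and residual domains, and 37.6% of them exceeded 6 kb against 7.01% of fast domains. On the log2 scale, fast domains were shorter than slow ones by a mean difference of -0.94 ± 0.31 (SD over 20 chromosomes), in 20 of 20 chromosomes (sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 2e-05 over 6 pairs of classes). Intermediate domains were shorter than slow ones by -0.88 ± 0.31 in 21 of 21 chromosomes, and slow domains were longer than residual ones by 0.86 ± 0.39 in 20 of 21 (adjusted permutation p = 2e-05 for each). The other pairs did not pass the test, with differences of -0.03 ± 0.13 for fast against intermediate (adjusted permutation p = 0.59), -0.04 ± 0.43 for fast against residual and -0.02 ± 0.41 for intermediate against residual (adjusted p = 0.822 for both). With mean in place of median width, fast domains were slightly shorter than intermediate ones (-0.07, adjusted permutation p = 0.0133).

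The share of slow domains rose with width. It was 11.2% among domains up to 1.5 kb, 20.7% at 3.3 to 6 kb, 45.0% at 6.3 to 12 kb and 56.4% above 12 kb. Within chromosomes, Spearman's rho between the class order (fast, intermediate, slow) and width averaged 0.284 ± 0.048 (SD) and was positive on 21 of 21 chromosomes (sign-flip permutation p = 1e-05, the smallest possible). The correlation is across domains, which are not independent replicates. Starting signal could not be compared, since the table holds none.

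**Figure D1:**
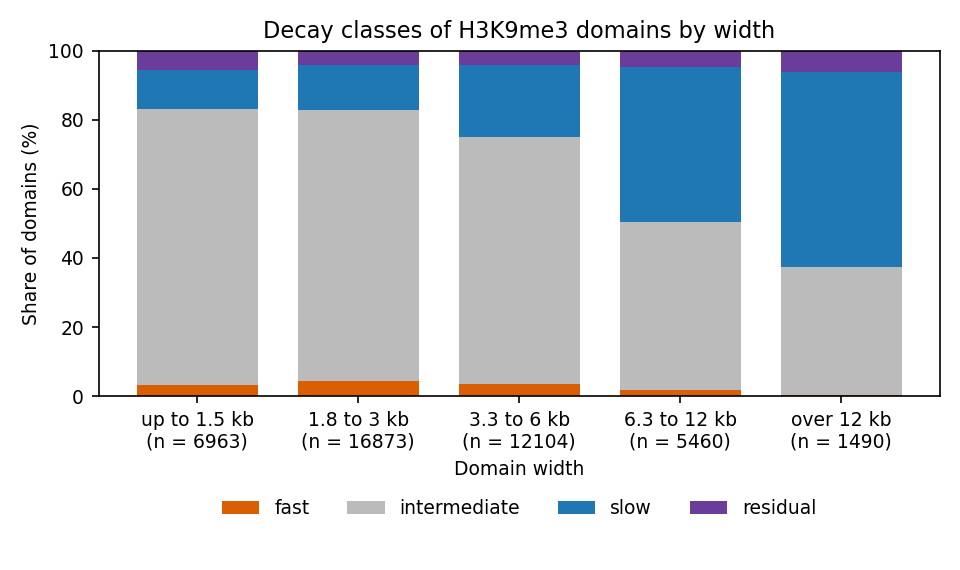
Stacked bars give the percent of domains in each decay class for 5 ranges of domain width, with the number of domains under each bar. The slow share grows from 11.2% in the shortest range to 56.4% above 12 kb, and the fast share is 0.201% there.

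The longest domains named individual loci. The longest slow domain ran for 121.5 kb on chromosome 10 (83373001 to 83494500) across D10Wsu102e and Aldh1l2, and others covered 60 kb on chromosome 17 (27247801 to 27307800) and 49.2 kb at Actg1, a cytoplasmic actin gene, on chromosome 11 (120300601 to 120349800). The longest residual domain covered 87.3 kb of chromosome 8 (123537301 to 123624600), where the annotation lists an array of 5S ribosomal RNA genes and only 2.29% of 31-mers were unique. A residual domain of 44.4 kb lay on Grb10, an imprinted gene for a growth factor receptor adaptor, on chromosome 11 (12005101 to 12049500), in sequence with 99.3% unique 31-mers. The longest fast domains were 16.8 kb in a stretch without genes on X (25461601 to 25478400) and 13.8 kb on chromosome 14 (32450701 to 32464500) at Chat and Slc18a3, the pair of genes for acetylcholine synthesis and its vesicular transport.

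Among protein-coding genes of at least 5 kb, those with the largest share of their body in fast domains were on several chromosomes. Shh, a secreted morphogen, had 48.7% of its body on chromosome 5 (28456815 to 28467256) in a fast domain of 6.6 kb, Kcna1, a voltage-gated potassium channel, had 35.1%, and Efnb1, an ephrin ligand on X, had 35.0%. Dmrtc1a on X reached 71.0% and Sept5, a septin gene on chromosome 16 that shares its fast domain with Gm49601 (80.5%), reached 50.8%; Zfp873, Hapln3, Adcy4 and C4b lay between 30.96 and 39.97%. The genes with the largest share in slow domains were nearly covered. Il3ra, an interleukin receptor gene on chromosome 14, Orc6, a subunit of the origin recognition complex on chromosome 8, and 6030452D12Rik were covered over 100%, Zfp629 over 99.2%, Ccdc110 over 96.4% and Psmg4, a proteasome assembly gene, over 95.2%. D10Wsu102e had 90.0%, Vmn2r35 86.5%, Flg2, an epidermal barrier gene, 84.6% and Zfp986 83.9%. These genes were picked for their coverage by the rule given under processing and were not tested one by one.

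Decay classes were unevenly spread over chromosomes. Chromosome 8 held 1302 slow domains among its 2869, or 45.4%, which is 2.22 times the share over all chromosomes (circular shift permutation p = 0.0001, the smallest possible; adjusted p = 0.0088 over 88 tests). On chromosome 11, 503 of 2280 domains were residual, or 22.1%, a ratio of 4.83 (adjusted permutation p = 0.0088). Intermediate domains were fewer on both, at 37.1% on chromosome 8 (adjusted permutation p = 0.0088) and 38.1% on chromosome 11 (adjusted p = 0.0352). On the 17 other autosomes the slow share ran from 16.0 to 21.4% and the residual share from 1.28 to 3.21%. These 4 calls were the ones past the threshold, and 9 tests were below 0.05 before adjustment. By covered length the chromosome 8 slow ratio was 1.64 (adjusted permutation p = 0.861) and the chromosome 11 residual ratio 4.57 (adjusted p = 0.144), and neither passed. The intermediate ratio of chromosome 11 did not pass by covered length either (0.514, adjusted permutation p = 0.0748). With the shortest domains left out, the residual ratio of chromosome 8 passed as well (4.02, adjusted permutation p = 0.0264).

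The remaining shares on these and the sex chromosomes did not pass the adjusted threshold. For a chromosome, the shift test ranks its block of domains against other stretches of as many domains. For chromosome 8 those stretches take in chromosome 11, and the reverse. Whether either passes therefore depends on the other too, and a miss does not show that a share is ordinary. The shifted stretches overlap one another, and some overlap the chromosome itself. Few separate stretches of that size exist, so a p-value that passes does not measure how rare a share is among chromosomes. Residual domains made up 17.4% of chromosome 8 (adjusted permutation p = 0.205) and slow domains 39.5% of chromosome 11 (adjusted p = 0.418). Fast domains numbered 2 on chromosome 8 and 9 on chromosome 11, or 0.214% of the 5149 domains there together, against 2.93% on the 17 other autosomes. On X, 438 of 2962 domains were fast, or 14.8%, 4.23 times the overall share (p = 0.007, adjusted permutation p = 0.109), and on Y 41 of 390, or 10.5% (adjusted p = 0.563). Near the centromere-proximal ends, slow domains were 1.16 times (adjusted permutation p = 0.109) and fast domains 0.747 times (adjusted p = 0.418) the overall share.

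**Figure D2:**
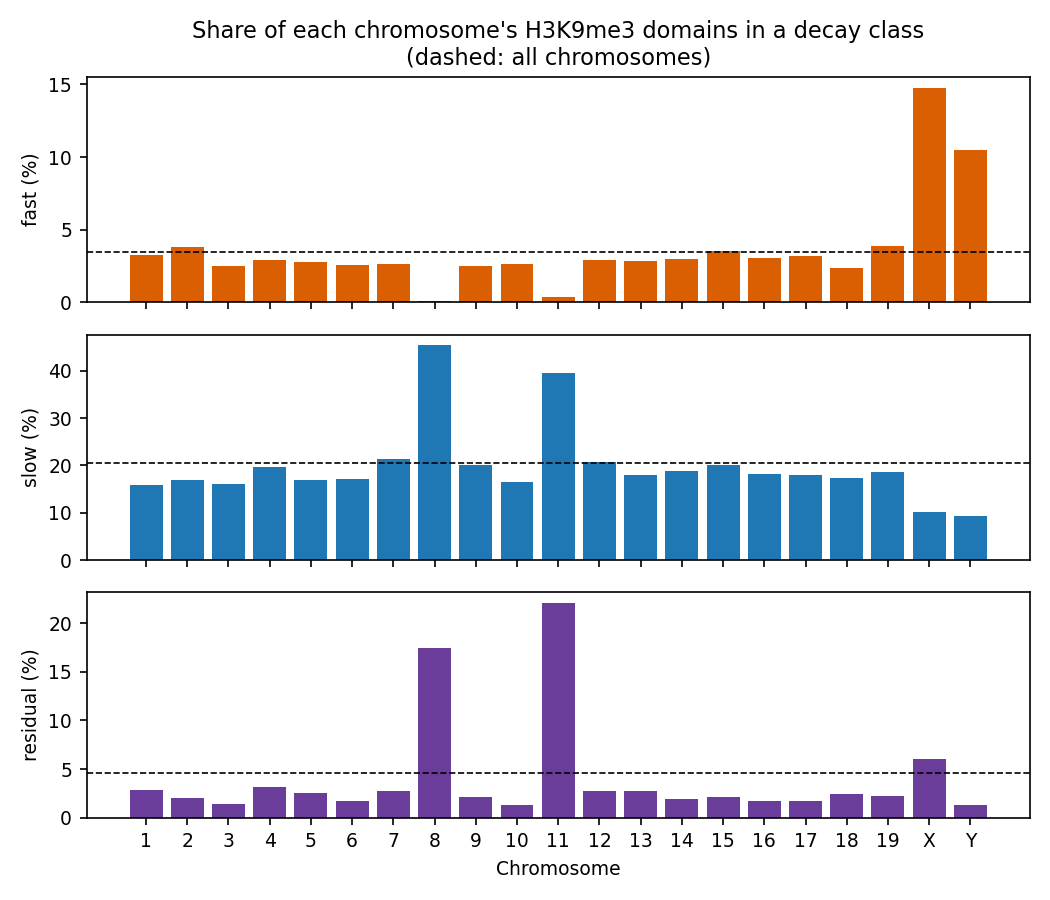
Bars give, for each chromosome, the percent of its domains that are fast (top), slow (middle) or residual (bottom), and the dashed line gives the percent over all chromosomes. Chromosomes 8 and 11 stand at 45.4 and 39.5% slow and 17.4 and 22.1% residual, and X and Y at 14.8 and 10.5% fast.

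The combined share of slow and residual domains set chromosomes 8 and 11 apart along their whole length, in a comparison added after the shares were seen. In windows of 20 Mb with at least 50 domains, slow and residual domains together made up 51.8 to 72.5% of domains in the 13 windows of chromosomes 8 and 11. In the 115 windows of the 17 other autosomes they made up 11.4 to 42.5%, with a median of 20.1%. The residual share alone overlapped between the groups. It was 6.72% in the chromosome 8 window from 60 Mb and 14.1% in the chromosome 7 window from 140 Mb. Slow domains on chromosomes 8 and 11 had a median width of 3.0 kb, against 5.1 kb on the other autosomes. Domain density was also highest there, at 22.2 domains per Mb on chromosome 8 and 18.7 on chromosome 11, against 12.6 to 17.5 on the other autosomes and X. These values describe the chromosomes and were not tested.

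**Figure D3:**
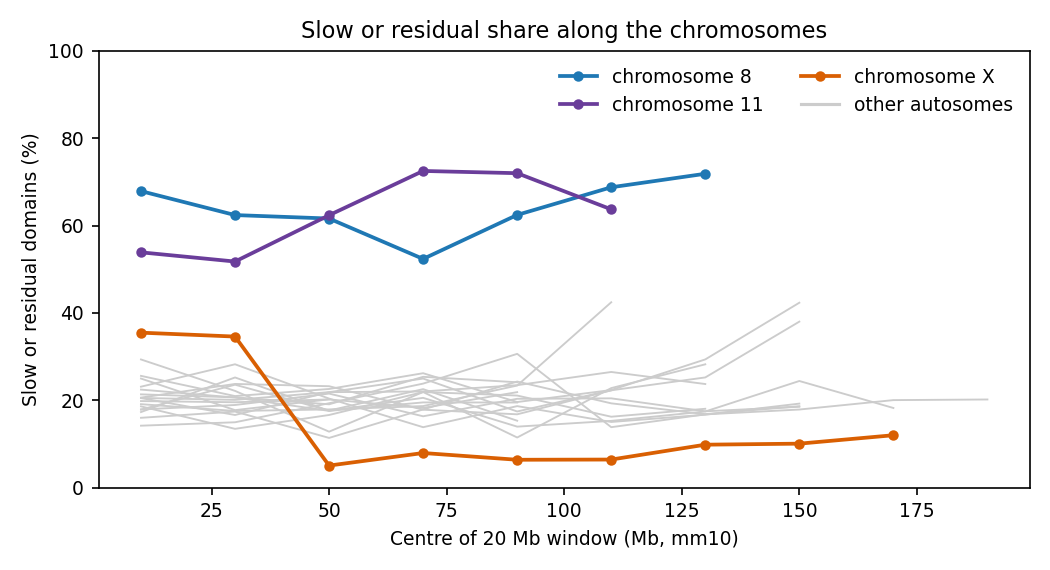
Lines give the percent of domains that are slow or residual in 20 Mb windows along each chromosome, against the centre of the window in Mb (mm10); Y is not drawn. Chromosomes 8 and 11 stay between 51.8 and 72.5%, above the 11.4 to 42.5% of the other autosomes.

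Neighbouring domains shared a class more often than expected. Of 42869 pairs of successive domains, 61.7% had the same class, against 58.4% after permutation within chromosomes (permutation p = 0.0001, the smallest possible; adjusted p = 0.000125). Residual domains were the most clustered, with 36.5% of their neighbours residual against 11.6% after permutation, a ratio of 3.16. Without chromosomes 8 and 11 that ratio was 9.62. With labels permuted over all domains instead of within chromosomes it was 8.01, and the ratio of fast domains was 2.32. Slow domains had 27.4% against 24.1%, intermediate domains 75.7% against 73.8% (adjusted permutation p = 0.000125 for each of the 3) and fast domains 8.08% against 6.58% (adjusted p = 0.0114). After joining same-class neighbours less than 5 kb apart, the ratios of fast (1.11) and slow domains (1.02) no longer passed (adjusted permutation p = 0.233 for both).

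Residual domains lay on genes far more often than the other classes. A gene body was overlapped by 60.6% of residual domains against 34.8% of all domains, a coding-gene exon by 28.3% against 6.91%, and a promoter by 16.8% against 3.03%. The ratios to all domains were 1.74, 4.09 and 5.53 (circular shift permutation p = 0.0001 for each, the smallest possible; adjusted p = 0.0002 over 16 tests). With promoters of 5 kb to either side, the residual promoter ratio was 3.64 (adjusted permutation p = 0.0002). Intermediate domains were less often on gene bodies (32.9%, ratio 0.945), exons (5.46%, 0.790) and promoters (2.18%, 0.719), each with adjusted permutation p = 0.0002. Fast and slow domains did not pass, with gene body shares of 33.9% (adjusted permutation p = 0.763) and 35.9% (adjusted p = 0.424). Without the sex chromosomes, fast domains were on gene bodies 1.14 times (adjusted permutation p = 0.00336) and on coding-gene exons 1.26 times (adjusted p = 0.0384) as often as all domains. With shifts within each chromosome, the exon ratio of fast domains was 1.33 (adjusted permutation p = 0.00347) and the promoter ratio of slow domains 0.847 (adjusted p = 0.00218) against the shifted mean. For slow domains the exon ratio was 0.780 when the domain midpoint had to lie in the exon (adjusted permutation p = 0.0227), on the other side of 1 from the ratio of 1.04 by any overlap. The promoter ratio of slow domains, 0.962 by any overlap, was 0.579 by midpoint (adjusted permutation p = 0.000178), and that of fast domains, 1.03, was 1.81 where at least 50% of the domain had to lie in the promoter (adjusted p = 0.0129).

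The residual share on promoters was similar on chromosomes 8 and 11 (16.7% of 1003 domains) and on the 17 other autosomes (18.3% of 774), while on X it was 10.1% of 178. The difference between these groups was not tested.

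**Figure D4:**
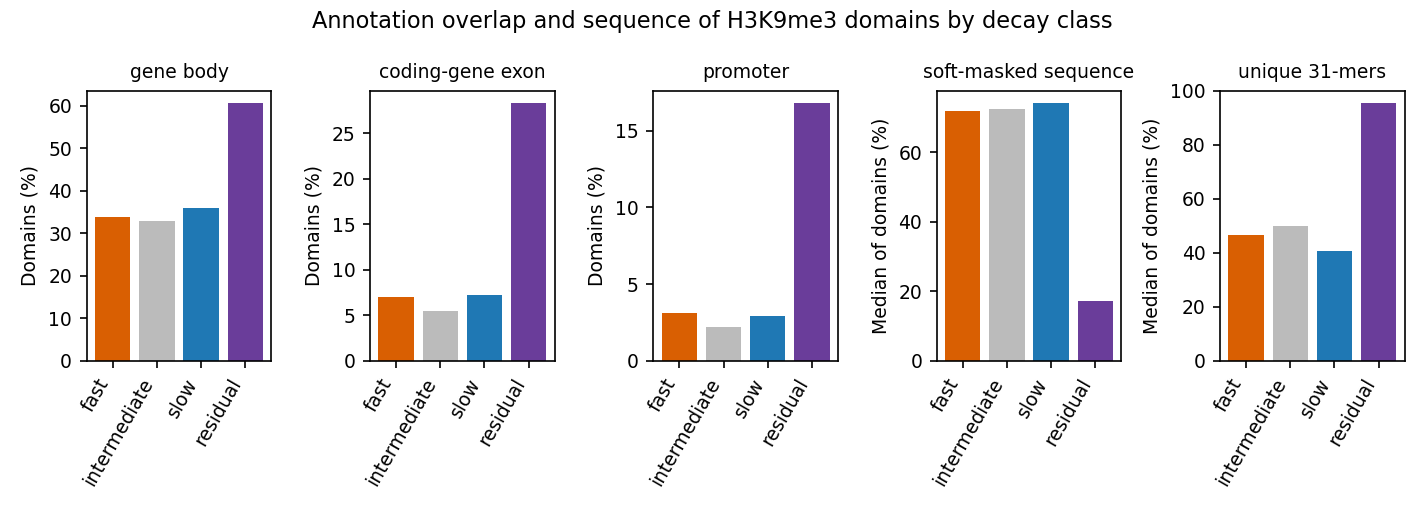
Bars give, per decay class, the percent of domains that overlap a gene body, a coding-gene exon or a promoter, and the median percent of soft-masked sequence and of unique 31-mers in a domain. Residual domains are at 60.6, 28.3 and 16.8% for the annotation and at 17.05% soft-masked sequence, against 71.7 to 74.0% in the other classes.

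Sequence separated the residual class from the rest, and the fast and slow classes from each other to a smaller degree. Fast domains had a higher GC content than slow ones by 0.751 ± 1.34 percentage points (SD over 20 chromosomes, lower in 4; adjusted p = 0.0232 over 3 measures, sign-flip permutation test). Their observed over expected CpG ratio was lower, at a median of 0.228 against 0.265, with a difference of -0.0518 ± 0.0450 in the same direction on 19 of 20 chromosomes (adjusted permutation p = 0.00036). With means in place of medians that difference was -0.0330 (adjusted permutation p = 0.00102). Their soft-masked share was lower by -17.2 ± 19.2 percentage points over per-chromosome medians, on 17 of 20 chromosomes (adjusted permutation p = 0.00144). Over all domains the soft-masked medians were 71.7% for fast and 74.0% for slow domains. The fast median was 84.4% on X and 53.7% on the 17 other autosomes.

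Residual domains held little repeat sequence at the median, in comparisons of the other pairs of classes chosen after the data were seen. Their median soft-masked share was 17.05%, with 95.2% unique 31-mers and a GC content of 47.8%, against 74.0, 40.7 and 43.5% in slow domains. The 178 residual domains on X were unlike the rest, with medians of 61.5% soft-masked sequence and 5.95% unique 31-mers. Slow domains exceeded residual ones in soft-masked share by 54.6 ± 11.7 percentage points on 21 of 21 chromosomes (adjusted p = 2.22e-05 over 20 tests, sign-flip permutation test). The share of unique 31-mers was lower in slow than in residual domains by -43.8 ± 22.6 percentage points, on 18 of 21 chromosomes (adjusted permutation p = 5e-05). Against intermediate domains, slow domains had a higher CpG ratio (0.265 against 0.225, higher on 19 of 21 chromosomes; adjusted permutation p = 2.22e-05) and fewer unique 31-mers (40.7 against 50.0%; adjusted p = 2.22e-05).

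Domains on genes that direct cell lineages were enriched in the residual class. Only 8 of these 34 genes had any domain, or 23.5%, near the 23.4% of all protein-coding genes, and 6 had a residual one. The list of 34 lineage regulators met 12 domains, of which 7 were residual, 12.8 times the share expected from all domains (circular shift permutation p = 0.0001, the smallest possible; adjusted p = 0.0076 over 76 tests of 19 lists), and 2 were intermediate (ratio 0.233, adjusted p = 0.0177). The residual domains lay on Gata6 (18, 11054401 to 11057700) and Gata4 (14, 63237901 to 63240900), transcription factors of endoderm and heart, and on Pax7 (4, 139828801 to 139830900 and 139764301 to 139766400), a factor of muscle and neural crest. The others, named after their values were seen, were on Pax6, an eye and neural factor, Tbx5, a heart and limb factor, and T, the mesoderm factor brachyury. Of the 7, 6 overlapped a coding-gene exon and 0 a promoter, and their median share of unique 31-mers was 100%. Residual domains are more frequent on genes in general, so the lists were also tested within narrower sets of domains, a choice made after the data were seen. Among the 14937 domains on a gene body the ratio was 7.34, and among the 2964 on a coding-gene exon, with 6 of 7 residual, it was 4.59 (adjusted permutation p = 0.0076 for both). The intermediate ratio did not pass among exon domains (0 of 7, adjusted permutation p = 0.106). The residual ratio was 23.005 without chromosomes 8 and 11 (adjusted permutation p = 0.0038) and 26.1 against the mean of shifts within each chromosome (adjusted p = 0.00253). By covered length it was 8.43 and did not pass (adjusted permutation p = 0.315). The intermediate ratio was 0.129 by covered length (adjusted permutation p = 0.0076) and 0.140 without chromosome 14 (adjusted p = 0.019). Pax3, a relative of Pax7, carried a slow domain of 17.1 kb, and the remaining domains on this list were at Runx1 and Gata4.

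Keratin and keratin-associated genes, which encode filament proteins of epithelia and hair, were also enriched in residual domains, with 14 of 25 domains (ratio 12.3, adjusted permutation p = 0.0177). Examples were Krt9 (11, 100188301 to 100193400), Krt34 (11, 100036501 to 100043100) and Krt36 (11, 100101601 to 100105800), the last 2 covered over 100% of their length. All 14 overlapped a coding-gene exon and 13 a promoter, and 12 of them were on chromosome 11. Among domains on a gene body the ratio was 7.05 (adjusted permutation p = 0.0342), and among domains on a coding-gene exon it was 2.996 and did not pass (adjusted p = 0.299). Without chromosome 15 the ratio was 18.4 (adjusted permutation p = 0.0285), and without chromosomes 8 and 11 it was 6.57 (adjusted p = 0.309). Without chromosome 11 the ratio was 4.65 (adjusted permutation p = 0.459); with labels shifted within each chromosome it was 4.45 against the shifted mean (adjusted p = 0.00608).

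Defensins, a family of antimicrobial peptides, were enriched in slow domains, with 14 of 22 domains (ratio 3.11, adjusted permutation p = 0.0361). Of the 14, 12 were in the cluster on chromosome 8, for example Defb38 (8, 19025101 to 19026600), and Defb41 and Defb44-ps were on chromosome 1. Without chromosome 8 the ratio was 2.14 (adjusted permutation p = 0.674), and without chromosome 1 it was 2.88 (adjusted p = 0.0973). Among domains on a coding-gene exon it was 2.89 and did not pass either (8 of 13 domains, adjusted permutation p = 0.106). The call was also lost by midpoint (2.72, adjusted permutation p = 0.271), by covered length (1.94, adjusted p = 0.413) and with shifts within each chromosome (1.63, adjusted p = 0.209).

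The 2-cell stage list, genes active in the early embryo and their pseudogenes, came close without passing, with 21 of 42 domains residual (ratio 10.9, p = 0.0033, adjusted permutation p = 0.0502). The result lay at the threshold: it passed without X (ratio 11.2, adjusted permutation p = 0.0195) and without chromosomes 8 and 11 (ratio 19.7, adjusted p = 0.0285). With shifts within each chromosome the residual ratio was 17.2 against the shifted mean (adjusted permutation p = 0.00253). The intermediate ratio, 0.233 and not past the threshold (adjusted permutation p = 0.0621), was 0.227 there and passed (adjusted p = 0.0057). The residual ratio also passed with any 1 of chromosomes 2 to 6, 8, 11, 12, 14 to 19 or Y left out (adjusted permutation p from 0.0355 to 0.0481). It did not pass without chromosome 1 (9.82, adjusted permutation p = 0.0977), 7 (10.7, adjusted p = 0.12), 9, 10 or 13 (adjusted p from 0.0545 to 0.0595), or by midpoint (9.63, adjusted p = 0.194). Its residual domains were on Sp110 on chromosome 1 (3 domains, 80.8% of the gene) and in the Obox cluster on chromosome 7 (18 domains, among them 1 of 6.6 kb shared by Obox1 and Obox3 at 15507601 to 15514200). On chromosome 7, 17 of the 18 overlapped an Obox4 pseudogene, and over both chromosomes 4 of 21 overlapped a coding-gene exon. Their median share of unique 31-mers was 3.70%. Among domains on a gene body the residual ratio was 6.29 (adjusted permutation p = 0.0814), and among those on a coding-gene exon it was 1.78 (4 of 12 domains, adjusted p = 0.934).

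The other 15 lists had no class past the threshold, and 12 of the 76 tests were below 0.05 before adjustment. Zinc finger genes met 262 domains, 74 of them slow (ratio 1.38, adjusted permutation p = 0.165), for instance Zfp935 and Zfp934, which share a slow domain of 24.6 kb on chromosome 13, and Zfp936 on chromosome 7. Olfactory receptors had 38 slow among 121 domains (ratio 1.54, adjusted permutation p = 0.131), and only 7.75% of their 1407 genes had a domain. Of 58 clustered protocadherin genes 37 had a domain, and 7 of 28 domains were residual (ratio 5.47, adjusted permutation p = 0.323), at Pcdhga1 to Pcdhga3 among others. The histone clusters had 2 fast among 4 domains (ratio 14.3, adjusted permutation p = 0.0651), at the testis histone genes Hist1h2aa and Hist1h2ba and at H1fnt; without the X chromosome the ratio was 25.1 (adjusted p = 0.0195).

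Germline genes often carried a domain, at 28 of 38 genes or 73.7%, against 23.4% of all 21938 protein-coding genes, a difference that was not tested. Of these, 21 had an intermediate domain, such as Sycp1, a component of the synaptonemal complex, with 6 intermediate domains over 17.2% of its body. Taf7l on X had a fast domain, Zcwpw1, Tuba3b and Mov10l1 had slow ones, and Tdrd6, Meioc and Spata22 had residual ones. Among 43 imprinted genes 21 had a domain. Kcnq1ot1, an imprinted long noncoding RNA, was 34.5% slow through a domain of 32.1 kb, Igf2 and Cdh15 carried slow domains, and Grb10 (31.04% of its body), Rasgrf1 and Ascl2 carried residual ones. Vomeronasal receptors had a domain at 134 of 565 genes, 109 of them with an intermediate one, and cytochrome P450 genes at 56 of 111.

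Pluripotency and ribosomal protein genes rarely carried a domain. Of 22 pluripotency genes 2 did, namely Esrrb with 2 intermediate domains and Tbx3 with a residual domain of 3 kb, and of 98 genes matched as ribosomal protein genes 3 did, among them the kinase gene Rps6kc1. Fibroblast markers, the common feeder cell type, had a domain at 4 of 18 genes, with a residual domain of 6.6 kb on Col1a1. Serpins had 11 of 68, major urinary proteins 9 of 49 and X-linked multicopy genes 9 of 87. None of these 6 lists passed in any class by the circular shift test, and the shares of genes with a domain were not tested.

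The H3K9 methylation machinery list had a domain at 3 of 21 genes, and Suv39h1 and Suv39h2 were not among them. Setdb1, a methyltransferase gene named in the genotype of the line, carried 2 residual domains of 0.9 kb (3, 95327101 to 95328000) and 0.6 kb (3, 95338501 to 95339100), both on coding-gene exons, and 1 intermediate domain of 1.5 kb. Atf7ip, a partner of Setdb1, had 1 intermediate domain of 1.2 kb at a promoter, and Pphln1, a subunit of the HUSH silencing complex, had 1 intermediate and 1 residual domain. Residual domains were 3 of the 6 on this list (ratio 10.9, adjusted permutation p = 0.127), and the ratio passed with shifts within each chromosome (29.1 against the shifted mean, adjusted p = 0.0139). Among domains on a gene body the ratio was 6.29 (adjusted permutation p = 0.201). The result rests on 3 domains: the pair on Setdb1 had 100% unique 31-mers and that on Pphln1 had 0%.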

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

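Residual domains were common on unplaced and unlocalized sequences, which none of the comparisons above used. Of the 149 domains on 35 such sequences, 39 were residual, or 26.2% (95% Wilson interval 19.8 to 33.8, for counting error only). The share on chromosomes 1 to 19, X and Y was 4.57%. The result is listed because a signal appeared in data that no comparison used, and the difference between the shares was not tested. The fast, intermediate and slow shares on these sequences were 5.37, 49.0 and 19.5%. No group of samples could be searched for libraries far from the rest, because the table has no values per library.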

How the results depend on the processing

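Leaving out chromosomes 8 and 11, shifting labels within each chromosome, testing lists among domains on genes or exons and the comparisons tied to them were chosen after the data were seen; the other alternatives were set before. Of 928 recomputed values, 825 kept their side of the threshold (or their count within 1.5 times). Direction had to be kept only where the main result passed, so values that missed the threshold both times could change sign. Direction and side of the threshold were kept under every alternative run by width of fast against slow domains and by base composition. The same held for the correlation of class order with width and for the residual enrichment on gene bodies, exons and promoters. Without chromosomes 8 and 11, residual domains numbered 957. By covered length, the ratio was 1.64 for slow on chromosome 8 and 4.57 for residual on chromosome 11, and 1 chromosome test passed. With labels permuted over all domains, which ignores clustering, the X fast ratio of 4.23 passed, and 67 chromosome tests did. By the circular shift test, 4 of 88 passed in the main analysis. Without chromosomes 8 and 11, 0 of 80 passed by the circular shift test. The adjustment there still ran over 88 tests, with the empty ones of those chromosomes kept. Joined neighbours gave ratios of 1.11 (fast) and 1.02 (slow), short of the threshold, as joining removes the closest same-class pairs. The gene body ratio of fast domains, 0.974 and not past the threshold, was 1.14 without the sex chromosomes, 1.15 with shifts within each chromosome and 0.953 to 1.11 with each chromosome left out in turn, past the threshold only without X (1.11) (18.9% of fast domains on X overlapped a gene, against 41.4% on the 17 other autosomes). The exon ratio of slow domains, 1.04, was 0.780 by midpoint, 0.729 by overlap of at least 50% and 0.923 with shifts within each chromosome; the cause was not tested. Gene list tests past the threshold numbered 4, against 16 by Fisher's exact test, which treats domains as independent, 7 without the sex chromosomes, 8 with shifts within each chromosome, 1 among domains on a coding-gene exon, where fewer domains are tested, and 3 to 7 with each chromosome left out in turn (3 without chromosome 1, 7 without X). No paired analysis was possible because the table has no columns per library. Alternatives planned for levels over time (a pseudocount, a filter on 0 h values, another scaling, replicates left out or blocked) were not run, since the table has no values per time. Depth behind each class is unknown, so how counting error moves domains between classes could not be measured.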

Other observations

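The windows along chromosomes 8 and 11, the comparison of X with Y and that of primer binding sites over all widths were chosen after the result was seen; the other tests of primer binding sites, and those of matched domains and residual bins were added after the table was seen but set before their results. Slow domains carried some retroviral primer binding sites more often than other classes. An endogenous retrovirus copies its genome from a host tRNA bound at an 18-nt site, and the site names the tRNA. Of 6 amino acids with a site in at least 100 domains, tRNA-Phe was the most frequent with 388 domains. The only tRNA-Phe site counted was TGGTGCTGAAACCCGGGA, from 1 tRNA gene, and the tRNA-Phe values describe this sequence only. It occurred in 198 slow domains, or 2.26%, 2.495 times the share of all domains (circular shift permutation p = 0.0001, the smallest possible; adjusted p = 0.0004 over 24 tests). It was rarer in intermediate (ratio 0.649, adjusted permutation p = 0.0004), fast (0.295, adjusted p = 0.0201) and residual domains (0.338, adjusted p = 0.016). Sites for tRNA-Pro were also more frequent in slow (105 of 176 domains, ratio 2.92, adjusted permutation p = 0.0004) and in residual domains (17 domains, ratio 2.11, adjusted p = 0.024). Sites for tRNA-Gly were more frequent in slow domains (82 of 219, ratio 1.83, adjusted permutation p = 0.0004). Sites for tRNA-Leu were more frequent in slow (40 of 134, ratio 1.46, adjusted permutation p = 0.0219) and less frequent in intermediate domains (ratio 0.846, adjusted p = 0.0201). Sites for tRNA-Lys were more frequent in fast domains (14 of 166, ratio 2.41, adjusted permutation p = 0.0108), and those for tRNA-Gln in intermediate domains (114 of 134, ratio 1.19, adjusted p = 0.00103). Longer domains can hold more sites, so the shares were also taken among domains of 6.3 to 12 kb on the 17 other autosomes. For tRNA-Gly they were then nearly equal, at 1.58% of slow and 1.45% of intermediate domains. They were 2.09 and 0.793% for tRNA-Pro, 0.509 and 2.42% for tRNA-Gln, and 0.356 and 0.485% for tRNA-Leu, where slow domains no longer had the higher share; none of these was tested. Of 60 fast domains in this range 0 had a tRNA-Lys site (95% Wilson upper limit 6.02%) against 2.16% of intermediate ones, so the fast excess is not seen there, with too few domains to show or exclude it. Only exact 18-nt matches were counted, so elements with a changed site were missed.

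In the same range of width, 105 of 1965 slow domains carried a tRNA-Phe site against 26 of 2270 intermediate ones, a ratio of 4.67, higher on 17 of 17 chromosomes (sign-flip permutation p = 2e-05). For tRNA-Lys sites the ratio was 0.189, with 8 of 1965 slow and 49 of 2270 intermediate domains. The slow share was higher on 0 of 17 chromosomes (sign-flip permutation p = 5e-05). Both ratios describe what domains of like width contain. The tests had been set to ask whether such elements account for the length of slow domains, but with width held in 1 range they cannot show that either way. Over all widths on the same autosomes, tRNA-Lys sites were in 15 of 6231 slow and 111 of 26376 intermediate domains, a ratio of 0.572, lower on 13 of 17 chromosomes and not past the threshold (sign-flip permutation p = 0.0770). For tRNA-Phe the ratio was 4.94, higher on 17 of 17 chromosomes (sign-flip permutation p = 2e-05), but longer domains can hold more sites. Exact sites were in 2.79% (tRNA-Phe) and 0.241% (tRNA-Lys) of these slow domains, too few to set their median width. Elements with a changed site were not counted, so the question stays open for both.

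Chromosomes 8 and 11 held many slow and residual domains. Base composition, repeat content, width and gene overlap do not account for this: matched to like domains of the other autosomes, the observed share was 3.08 times the expected one (2.96 to 3.20 over 200 resamples). Only the other autosomes were resampled, so the interval leaves out any spread of chromosomes 8 and 11. A higher number of copies of these whole chromosomes in the cells may be involved, since the lowest of their 20 Mb windows reached 51.8%, above the highest of the other autosomes at 42.5%. Copy numbers were not measured here, the way a copy number would pass into the classes is not given in the sources used here, and a chromosome-wide difference in decay stays open; no biological explanation was tested.

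Fast domains were frequent on X. The observed share was 5.52 times that of like domains of the other autosomes (4.98 to 6.20 over 200 resamples of those autosomes, with X held fixed), so base composition, repeat content, width and gene overlap do not account for it. A lower number of copies per cell may be involved: on Y the fast share was 10.5% (95% Wilson interval 7.84 to 14.0, for counting error only), also above the highest of the other autosomes at 3.87%. In 20 Mb windows, looked at after the result was seen, the fast share on X ran from 8.33 to 16.6%. The lowest X window, from 160 Mb, lay below the chromosome 2 window from 160 Mb at 8.97%. X was therefore not set apart along its whole length, as chromosomes 8 and 11 were. The X and Y shares did not pass the adjusted circular shift test, and copy numbers were not measured here. No biological explanation was tested.

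Residual domains also gathered in 6 bins of 2 Mb outside chromosomes 8 and 11, with at least 30% and at least 6 residual domains each, among them X from 2 to 6 Mb and from 30 to 34 Mb and chromosome 1 from 84 to 86 Mb. Reads shared between near-identical copies in the reference may be behind most of them. The 185 residual domains there had a median of 6.67% unique 31-mers against 96.5% in the 1775 elsewhere, a difference of -89.8 percentage points. Of those 1775, 1003 lay on chromosomes 8 and 11, while most of the 185 lay on X. The comparison is thus largely of X with autosomes. The bin on chromosome 12 from 110 to 112 Mb, with 10 residual domains and a median of 96.4%, is not covered by that explanation. Extra copies that these cells have and the reference lacks cannot be told apart from it, with 0 values of input coverage in the table. The other classes in the bins were not compared. On X, median unique shares were also low in fast (33.3%), intermediate (25.0%) and slow domains (10.0%). Low uniqueness therefore does not show why domains in the bins were residual. No biological explanation was tested.

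Outside these bins and chromosomes 8 and 11, 772 residual domains remained. On the 17 other autosomes, residual domains had a median of 94.9% unique 31-mers and 16.1% soft-masked sequence, and 29.97% of them overlapped a coding-gene exon.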
